A study of Drosophila melanogaster with 6 samples.

How the data were processed

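The study measured RNA from brains of Drosophila melanogaster larvae in 3 control and 3 DNMT3L samples, grouped by the genotype in the labels. Per the labels' protocols, total RNA was extracted with TRIzol or a column kit, and libraries were made by random priming after poly(A) isolation or rRNA removal. Which of these was used for which library is not given in the sources used here. Per the submitters' processing notes, the tools included bcl2fastq 2.17.1.14, cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2, with the builds BDGP6 and dm6. The role of each tool, the strand setting of the counting and the annotation release are not given in the sources used here. The deposited table gives read counts per gene for each sample as whole numbers, and per the file headers it also holds FPKM values, exonic sizes, coordinates and functional terms. The deposited FPKM could be recomputed from the counts, the exonic size and the total count for 100% of values in each library. Of 17737 gene identifiers, 17599 were found in the Ensembl release 115 annotation, 17465 of them (99.2%) with identical coordinates, and coordinates are printed as the deposited table gives them.

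Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with low counts were removed with filterByExpr (8242 removed, 9495 kept), libraries were scaled by TMM, and the groups were compared with glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The plan held limma on log2(FPKM + 1) for a table without counts and edgeR for a table with counts, and the table held counts. Standard errors of log2 fold changes are those implied by the F statistic. CPM values are scaled by TMM. The common biological coefficient of variation was 31.5%, and 24.4% without control 1. Total counts between 17928420 and 19251845 put a floor of 3 counts at 0.156 to 0.167 CPM before TMM scaling, and this floor covers counting error only. On simulated data with the real means, library sizes and spread, with 200 genes changed, the edgeR step on 9495 genes recovered 12% of 2-fold, 74% of 4-fold, 90% of 8-fold and 98% of 16-fold changes, with 4 false calls. Genes were drawn independently there, without deviations that the genes of a library share. These rates are therefore not the power of the test on the real data, where CG32581 at 35.6-fold missed the threshold (edgeR adjusted p = 0.0538).

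The gene lists, the tests, the groups and the rule for the genes named in the text were fixed before the data were examined. There were 43 lists, of which 40 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over lists. Of 811 list entries, 5 matched no gene. The rule named the 24 genes with the lowest p (since none passed), up to 4 members per list past the threshold or else its 2 members with the highest mean, and every detected member of the driver, marker and balancer, Hox and male sex chromosome lists. Genes named outside this rule are said to be so, or stand beside a gene of the rule as its overlapping or paralogous partner. The immune genes AttA, Drs, Drsl5, AttB, Dro and CecC and the genes called only after removal of the length trend were chosen after their values were seen. Alternatives were DESeq2 1.42.0, other size factors, no low-count filter, a replicate block, each library left out, and limma on FPKM with other pseudocounts, filters, scalings and variance models. Alternatives added after the data were seen were the removal of each library's loess trend (span 0.5) of log2 deviation on log2 exonic size, the exclusion of both libraries numbered 1, limma on log2(FPKM + 1) with the planned settings, and voom with library quality weights. With 0 genes called by edgeR, the planned tests of chromosome arms and functional terms had no genes to test, and they were run on the DESeq2 calls instead. GC content was not analysed here. Not every gene that the rule named is reported here. Random gene lists, bootstrap intervals and Fisher's exact tests used Python 3.11.15 with scipy 1.17.1, and figures used matplotlib 3.10.9.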

Results

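RNA sequencing measured gene expression in brains of Drosophila melanogaster at the third larval instar, in 2 groups of 3 libraries. The control group carried elavC155-Gal4, a driver that expresses the yeast transcription factor Gal4 in neurons. The DNMT3L group came from a cross of that driver to flies with a UAS-DNMT3L transgene, in a stock with the balancer chromosomes CyO, TM2 and TM6B. DNMT3L is a mammalian protein without catalytic activity that binds DNA methyltransferases. The deposited table lists 17737 genes, of which 3833 had no read in any library. Total counts per library were 19251845, 18183491 and 18297411 for control libraries 1 to 3 and 17938564, 17928420 and 18399526 for DNMT3L libraries 1 to 3. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these samples. Values below are TMM-scaled CPM, read counts relative to library size, as mean ± SD with n = 3 per group, and the transgene's own expression was not analysed here.

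The comparison of DNMT3L with control brains asks which transcripts differ between the driver and its cross to the UAS-DNMT3L stock. In that stock the transgene lies over CyO, and the genotype labels do not say that larvae with the transgene were selected. The clearest differences were a set of genes with few reads in the controls. CG32581 was at 0.213 ± 0.0985 CPM in controls and 7.75 ± 1.36 CPM in DNMT3L brains, 35.6-fold higher. CG14445 was at 1.25 ± 0.282 against 17.8 ± 4.74 CPM, and Fbp2, a gene of the larval fat body, at 0.931 ± 0.527 against 20.4 ± 3.75 CPM. As groups, genes of neurotransmitter receptors, ion channels and synaptic release had higher levels in DNMT3L libraries, and ribosomal protein, cuticle and muscle genes had lower levels, by their medians. None of these 6 lists was called with an estimated correlation (adjusted p = 0.54 for each), and control 1 stood apart from the other controls in most of them. No single gene passed the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment. edgeR called 0 of 9495 genes tested, with 1427 at an unadjusted p under 0.05, DESeq2 called 260 genes (93 higher, 167 lower), and limma on log2(FPKM + 1) called 10, all higher.

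Among the 24 genes with the lowest edgeR p, all of which missed the threshold, 18 were higher in DNMT3L and 6 lower, and in each of them the groups did not overlap. Over all genes tested, the groups did not overlap for 2667 (28.1%), against 10% by chance for a single gene, with 1328 higher and 1339 lower. Genes moved together across libraries, so this share can differ widely between groupings and no p-value goes with it. Groupings that mixed control and DNMT3L libraries gave 18 to 1045 genes at an unadjusted edgeR p under 0.05, against 1427. DESeq2 called all 24. CG32581 lies on chromosome X from 15796908 to 15799162 on the minus strand of the BDGP6 build. Its log2 fold change was 5.15 ± 0.43 (SE), with a Benjamini-Hochberg adjusted p of 0.0538 by edgeR and 4.17e-18 by DESeq2. The pseudogene CR44383, at 15796477 to 15796897 on the opposite strand beside it, had 2 reads over the 3 controls and 3.19 ± 1.03 CPM in DNMT3L. Without a known strand setting, its reads may belong to the same transcript as CG32581, which was not tested, so the 2 may not be separate genes here. CG14445, on X from 6237315 to 6240558, had a log2 fold change of 3.82 ± 0.33 (edgeR adjusted p = 0.0538), and CG9123, also on X, had 2.89 ± 0.29 (edgeR adjusted p = 0.0631). The noncoding RNA CR46064 on 2R was at 1.26 ± 0.461 against 14.8 ± 0.828 CPM, and CG12592 on 3R at 0.471 ± 0.309 against 10.2 ± 1.42 CPM. CG12096 on X was at 3.06 ± 0.377 against 18.3 ± 4.17 CPM. Its exons overlap Lgr4 on the opposite strand, and the strand setting of the counting is not given in the sources used here, so its reads cannot be assigned with certainty.

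Ada1-1, CR46123 and CG3397 had no read in any control library. Against a floor of 3 counts per library, Ada1-1 (3.88 ± 1.08 CPM in DNMT3L) was at least 22.6-fold higher, CR46123 (3.68 ± 1.27 CPM) at least 21.4-fold and CG3397 (0.956 ± 0.056 CPM) at least 5.56-fold. Ada1-1 has a close copy, Ada1-2, at 7.83 ± 4.39 against 5.47 ± 2.07 CPM, and overlaps CG18787 on the opposite strand, so its level is uncertain. Unc-115b, which likewise has a paralog, Unc-115a, had 3 reads over the controls and 1.71 ± 0.181 CPM in DNMT3L. Grik, a glutamate receptor subunit gene, was at 0.301 ± 0.105 against 1.76 ± 0.185 CPM, and the adenylate cyclase gene ACXD at 0.246 ± 0.0556 against 1.55 ± 0.39 CPM. The other higher genes of the 24 were DptA (below), CR45674, CG42329 and CG31030, the last at 28.6 ± 1.03 against 50.9 ± 2.96 CPM. The 6 lower genes were CG44250 (log2 fold change −3.70 ± 0.56), Mec2 (−2.71 ± 0.43), CG15212 (−2.49 ± 0.39), CG13722 (−1.82 ± 0.26), CG3649 (−1.78 ± 0.27) and pst (−1.32 ± 0.22), with edgeR adjusted p between 0.2 and 0.228. The exons of Fbp2, CG44250, CG3649, CR46064 and Unc-115b also overlap a neighbouring gene.

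**Figure D1:**
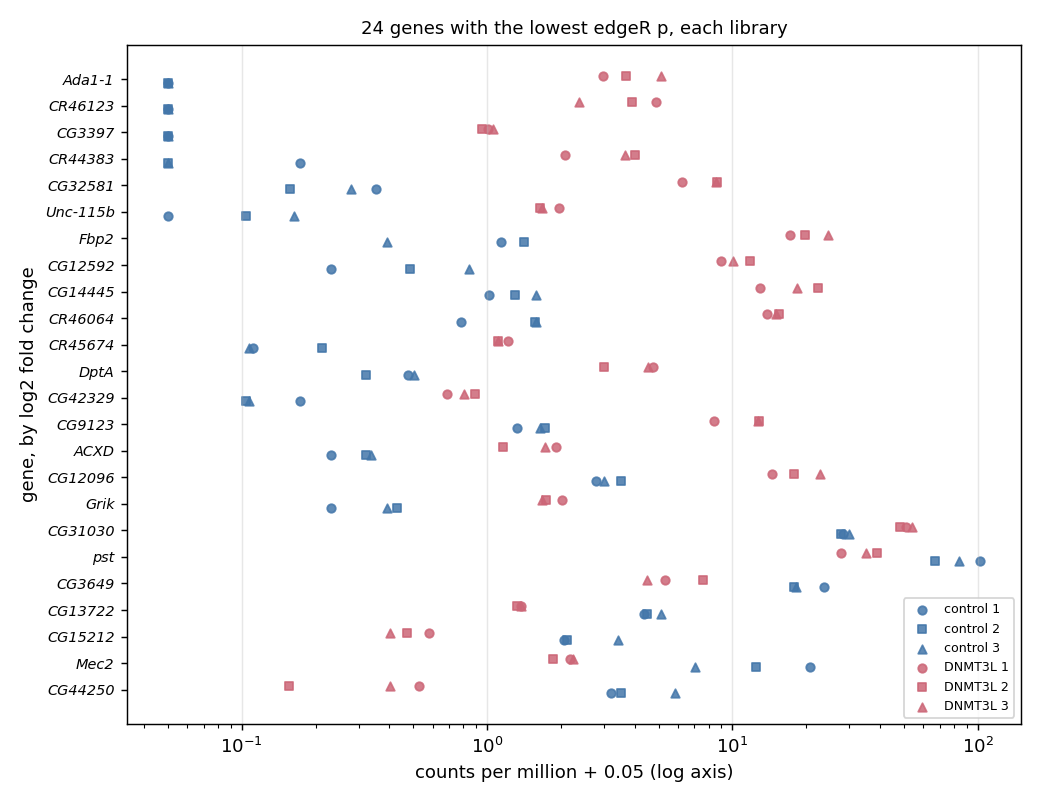
TMM-scaled CPM plus 0.05, on a log axis, for the 24 genes with the lowest edgeR p, ordered by log2 fold change, with 1 point per library (3 control, 3 DNMT3L). The 2 groups do not overlap for any of the 24 genes, and Ada1-1, CR46123 and CG3397 have 0 reads in every control library.

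Of 40 lists of genes fixed by function or tissue and tested by camera with a preset correlation of 0.01, 22 were called, 12 higher and 10 lower in DNMT3L. None of the 22 was called with an estimated correlation, where their adjusted p lay between 0.44 and 0.7, and none by fry, a test of whether a list's genes move one way on balance. The mixed fry test, of change in either direction, passed for innate immunity (adjusted p = 0.0042), gut (adjusted p = 0.024) and fat body (adjusted p = 0.032). No member of any list passed edgeR over all genes. All 31 neurotransmitter receptor genes tested had positive log2 fold changes, with a median of 1.15, or 2.23-fold (camera adjusted p = 5.99e-14; adjusted p = 0.54 with an estimated correlation). GABA-B-R2, a subunit of the metabotropic GABA receptor, was at 46.7 ± 17.4 CPM in controls and 82.6 ± 20.5 CPM in DNMT3L, and the acetylcholine receptor subunit gene nAChRalpha2 at 30.1 ± 8.4 against 43.8 ± 6.63 CPM. For ion channels, 20 of 22 genes were positive with a median of 1.27 (camera adjusted p = 1.31e-08; adjusted p = 0.54 with an estimated correlation), among them Ih at 28.6 ± 7.91 against 51.6 ± 6.98 CPM, whose log2 fold change of 0.85 was 0.02 with the length trend removed. All 20 genes of synaptic release were positive with a median of 1.06 (camera adjusted p = 2.55e-08; adjusted p = 0.54 with an estimated correlation). Of these, unc-13, needed for vesicle priming, was at 116 ± 59.4 against 301 ± 148 CPM, and Csp, a synaptic vesicle chaperone, at 169 ± 37.8 against 257 ± 5.9 CPM. All 14 genes of transmitter synthesis and transport were positive with a median of 0.90 (camera adjusted p = 3.67e-05; adjusted p = 0.54 with an estimated correlation). Gad1, the enzyme that makes GABA, was at 37.8 ± 14.1 against 80.5 ± 21.8 CPM, and the glutamate transporter gene VGlut at 65.2 ± 26.2 against 123 ± 19.4 CPM.

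Control library 1 lay apart for these groups. Its median deviation from the 6-library mean was −1.95 for receptors, against 0.09 and −0.25 for the other controls. Without it the group medians were 0.77 for receptors, 0.92 for ion channels, 0.66 for synaptic release and 0.54 for transmitter genes. Neuropeptide genes were positive for 29 of 39 with a median of 0.44, which was 0.40 without control 1 (camera adjusted p = 0.000377; adjusted p = 0.54 with an estimated correlation). Nplp1, a neuropeptide precursor, was at 101 ± 21.9 against 164 ± 8.7 CPM, and Phm, an enzyme of peptide amidation, at 138 ± 6.53 against 128 ± 2.3 CPM. Genes of axon guidance and adhesion had a median of 0.67, which was 0.33 without control 1 (camera adjusted p = 1.68e-05; adjusted p = 0.7 with an estimated correlation), with Nrt at 337 ± 153 against 595 ± 193 CPM. Their camera adjusted p was 0.79 without control 1 and DNMT3L 1.

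The lists for neuroblasts, the neural stem cells, and for temporal patterning were called too. The neuroblast list also holds genes that act in neuroblast daughters, such as pros. Temporal patterning genes were positive for 17 of 19 with a median of 0.71, which was 0.40 without control 1 (camera adjusted p = 3.67e-05; adjusted p = 0.54 with an estimated correlation). Adjusted over the list alone, 1 member passed edgeR, the transcription factor gene cas, at 56.8 ± 7.17 against 105 ± 6.02 CPM (edgeR adjusted p = 0.0139 over the list, 0.239 over all genes). That gene and the other members that passed over a list alone are named here after their values were seen. Neuroblast genes were positive for 17 of 19 with a median of 0.42, which was 0.25 without control 1 (camera adjusted p = 0.000377; adjusted p = 0.54 with an estimated correlation). In this list pros, which promotes differentiation of neuroblast daughters, was at 247 ± 154 against 803 ± 491 CPM, with DNMT3L 1 at 1370 CPM, and its log2 fold change of 1.70 was 0.82 with the length trend removed. Polycomb and trithorax genes had a median of 0.53, which was 0.34 without control 1 (camera adjusted p = 0.000167; adjusted p = 0.54 with an estimated correlation). The chromatin remodeller gene kis was at 268 ± 158 against 579 ± 265 CPM, and Caf1-55 at 387 ± 25.7 against 372 ± 24.9 CPM. Heterochromatin and histone modifier genes had a median of 0.47, which was 0.26 without control 1 and 0.04 with the length trend removed (camera adjusted p = 0.00401; adjusted p = 0.7 with an estimated correlation), with the histone deacetylase gene HDAC1 at 373 ± 6.38 against 393 ± 52.5 CPM. Circadian genes had a median of 0.53, which was 0.29 without control 1 and 0.09 with the length trend removed (camera adjusted p = 0.0176; adjusted p = 0.54 with an estimated correlation), and without control 1 their camera adjusted p was 0.116. Without both libraries 1 the camera adjusted p was 0.577 for each of these last 2 lists. Among 4 genes related to DNA methylation, too few for camera, Tet was at 189 ± 119 against 451 ± 220 CPM and MBD-R2 at 97.0 ± 14.0 against 110.0 ± 10.5 CPM.

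**Figure D2:**
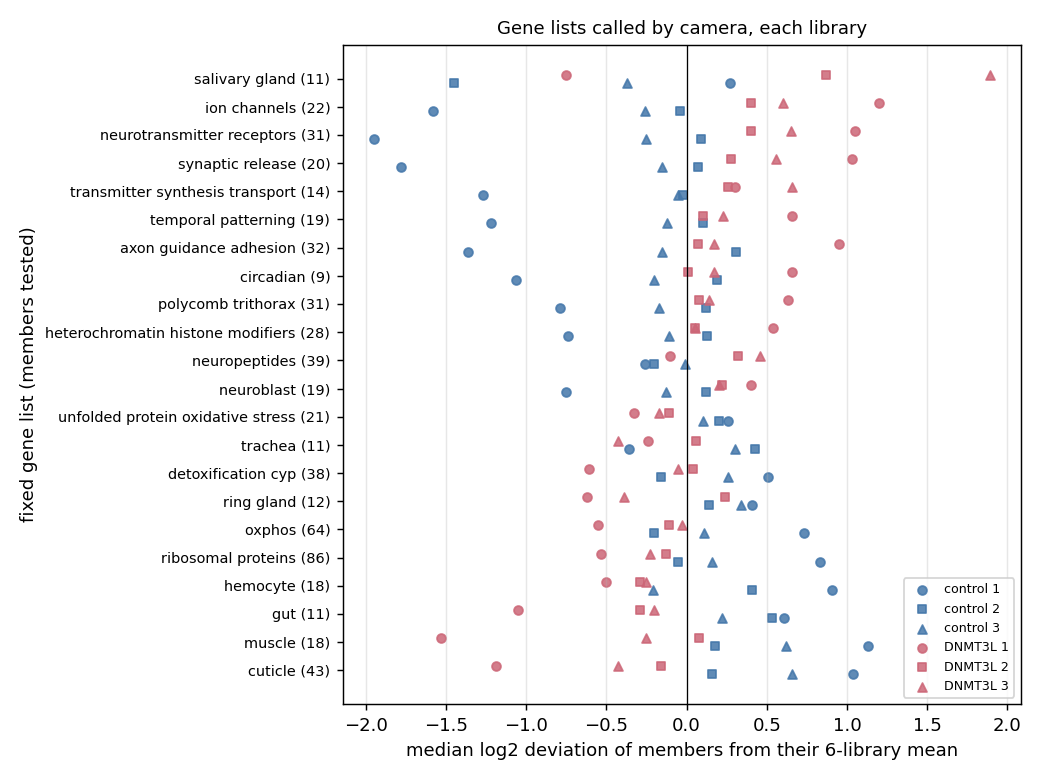
Median log2 deviation of each list's members from their 6-library mean, with 1 point per library, for the 22 lists that camera called, ordered by median log2 fold change. Control 1 lies at −1.95 for neurotransmitter receptors and at 0.83 for ribosomal proteins, and DNMT3L 1 at 1.05 and −0.53.

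All 86 ribosomal protein genes tested were lower, with a median log2 fold change of −0.66, which was −0.36 without control 1 (camera adjusted p = 1.49e-19; adjusted p = 0.54 with an estimated correlation). RpL4 was at 5780 ± 1560 against 3960 ± 631 CPM. Genes of oxidative phosphorylation had a median of −0.48, which was −0.19 without control 1 (camera adjusted p = 1.33e-07; adjusted p = 0.7 with an estimated correlation), with ATPsynC at 1880 ± 372 against 1790 ± 318 CPM. Their camera adjusted p was 0.79 without both libraries 1. The list of unfolded protein and oxidative stress genes had a median of −0.29 (camera adjusted p = 0.0011; adjusted p = 0.44 with an estimated correlation). Adjusted over the list alone, 4 of its members passed edgeR, all lower and all enzymes of peroxide or glutathione metabolism. These were catalase (Cat) at 264 ± 14.2 against 181 ± 7.02 CPM, GstD1 at 1290 ± 444 against 540 ± 190 CPM, GstE1 at 56.4 ± 23.3 against 19.6 ± 2.98 CPM, and Prx2540-1, which has a near-identical copy, at 0.873 ± 0.137 against 0.0851 ± 0.105 CPM. The list holds other genes of glutathione metabolism, which did not pass. Detoxification P450 genes had a median of −0.39 (camera adjusted p = 0.00218; adjusted p = 0.7 with an estimated correlation), with Cyp6a17 at 97.8 ± 38.2 against 31.8 ± 11.7 CPM, and their camera adjusted p was 0.577 without both libraries 1.

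Lists of markers of tissues other than the brain were also called by camera with the preset correlation, though no member passed edgeR over all genes. Cuticle genes were negative for all but 1 of 43, with a median of −1.32, which was −1.09 without control 1 (camera adjusted p = 1.84e-10; adjusted p = 0.54 with an estimated correlation). Lcp4 was at 287 ± 212 against 85.2 ± 49.7 CPM. Muscle genes had a median of −1.22, which was −0.85 without control 1 (camera adjusted p = 0.000182; adjusted p = 0.54 with an estimated correlation), with Act57B at 198 ± 53.5 against 83.0 ± 41.1 CPM. Medians were −0.99 for gut genes, −0.86 for hemocyte genes, −0.46 for ring gland genes and −0.37 for tracheal genes, with camera adjusted p of 0.00127, 0.0011, 0.00425 and 0.0324. With an estimated correlation their adjusted p were 0.44, 0.54, 0.54 and 0.54. Adjusted over the list alone, 3 tracheal genes passed edgeR, the chitin deacetylase genes verm (294 ± 17.8 against 157 ± 42.1 CPM) and serp (145 ± 19.1 against 77.4 ± 18.4 CPM), and Gasp. Salivary gland genes were positive for all 11 with a median of 1.35 (camera adjusted p = 0.00814; adjusted p = 0.54 with an estimated correlation), but the groups overlapped for every member. The glue protein gene Sgs3 was at 10.6 ± 8.97 against 41.5 ± 32.9 CPM. Its log2 fold change was 1.97, 2.93 without control 1 and 3.40 without both libraries 1, where edgeR called it (adjusted p = 0.0125).

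Fat body and immune genes went both ways. The fat body list was not called (camera adjusted p = 0.124). With the length trend removed it was called as lower (camera adjusted p = 0.0421), but not with an estimated correlation there (adjusted p = 0.6). Of its 12 members, 6 passed edgeR adjusted over the list alone. Fbp2 and the lipophorin gene apolpp were higher, and the storage protein genes Lsp1beta, Lsp1gamma and Lsp2 and the storage protein receptor gene Fbp1 were lower, Lsp1gamma at 517 ± 155 against 176 ± 32.5 CPM. With the length trend removed the log2 fold change of apolpp went from 0.82 to 0.00, while that of Fbp2 was 4.74. In the innate immunity list 1 of 21 members passed over the list alone, DptA, which encodes the antimicrobial peptide diptericin, at 0.384 ± 0.0988 against 4.05 ± 0.945 CPM (edgeR adjusted p = 0.00141 over the list, 0.0794 over all genes). In contrast AttA, an attacin gene, was at 1.71 ± 0.0945 against 0.592 ± 0.373 CPM and Drs, which encodes drosomycin, at 2.97 ± 0.939 against 1.00 ± 0.393 CPM (edgeR adjusted p of 0.332 and 0.322). Of other antimicrobial peptide genes, Drsl5 (log2 fold change 2.05), AttB (0.21) and Dro (0.19) were higher and CecC (−0.32) lower, none of them called.

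Glial genes were not called, with a median of 0.17 (camera adjusted p = 0.349), and Obp44a, an abundant transcript in this list, was at 11900 ± 3560 against 10000 ± 1680 CPM. Cell cycle genes had a median of −0.09 (camera adjusted p = 0.506), with polo at 352 ± 14.5 against 345 ± 37.4 CPM, and apoptosis genes −0.03 (camera adjusted p = 0.929). Hox genes had a median of 0.63 (camera adjusted p = 0.19), which was 0.22 without control 1 and 0.03 with the length trend removed, and the direction of the camera test turned without both libraries 1. Of 8 Hox genes 2 were negative, lab at 2.80 ± 0.509 against 2.09 ± 0.646 CPM and Dfd at 3.57 ± 0.541 against 3.23 ± 0.484 CPM. Antp was at 21.4 ± 8.71 against 33.6 ± 4.48 CPM, abd-A at 12.3 ± 7.67 against 20.7 ± 7.75 CPM and Ubx at 10.1 ± 5.5 against 11.8 ± 3.02 CPM. Without control 1 the log2 fold change of abd-A went from 0.75 to 0.33, that of Antp from 0.65 to 0.36 and that of Ubx from 0.22 to −0.08. Among genes tied to the driver and the marked chromosomes, elav, the host gene of the driver insertion, was at 136 ± 89.8 against 328 ± 128 CPM (edgeR adjusted p = 0.334). Its log2 fold change of 1.27 was 0.83 without control 1, at 36.8 CPM, and 0.65 with the length trend removed. The gene w, for eye colour and carried by transgenes, had a log2 fold change of −0.52 ± 0.38 (SE). The male dosage compensation RNA roX1 was at 352 ± 193 against 482 ± 116 CPM, and roX2 at 34.5 ± 12.7 against 19.5 ± 8.23 CPM. The 18 lists that were not called had camera adjusted p between 0.124 and 0.929, and 3 of the 43 lists had too few members for camera.

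Control 1 and DNMT3L 1 had opposite trends with gene length. In control 1 the shortest decile of genes lay at a median of 0.65 above its 6-library mean on the log2 scale and the longest decile at −1.12, while in DNMT3L 1 these were −0.48 and 0.84. The median log2 fold change between groups went from −0.42 for the shortest to 0.67 for the longest decile. With each library's length trend removed, an analysis added after the data were seen, edgeR called 12 genes, 11 higher and 1 lower. These were CG32581 (edgeR adjusted p = 0.0081), CG14445, CR46064, CG9123, Fbp2, CG12592, CG12096, Ada1-1, CR44383, DptA and Fili, at 13.1 ± 4.37 against 34.5 ± 7.28 CPM, and the lower gene pio, at 192 ± 32.8 against 121 ± 23.4 CPM. In that fit camera called 20 lists, and none with an estimated correlation. Median log2 fold changes there were 0.88 for receptors, 0.73 for synaptic release, 0.62 for ion channels, 0.68 for neuropeptides, 0.21 for axon guidance, 0.15 for polycomb and trithorax, −0.31 for ribosomal proteins and −0.16 for oxidative phosphorylation. Single genes moved too, unc-13 from 1.38 to 0.48, kis from 1.11 to 0.28 and Tet from 1.26 to 0.49. In this fit heterochromatin modifiers (camera adjusted p = 0.591), circadian genes (0.419), axon guidance (0.0505) and gut (0.0547) were no longer called. Fat body (camera adjusted p = 0.0421) and eye disc genes (0.0184) were newly called, both as lower. The first principal component held 66.2% of the variance and set control 1 (−81) apart from DNMT3L 1 (61.2), and on the second, with 12.7%, control 1 (5.1) lay above DNMT3L 1 (−5.4) while the other controls (−27.3 and −17.6) lay below the other DNMT3L libraries (26.2 and 19.1). The count of 12 fell to 0 when control 3, DNMT3L 2 or DNMT3L 3 was left out and was 2 without control 2 or DNMT3L 1. Because the groups differed in the chromosomes of the crossed stock as well as in the transgene, the comparison does not separate these differences. The genotype labels name no cross for the control group, so the number of driver copies may differ too.

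**Figure D3:**
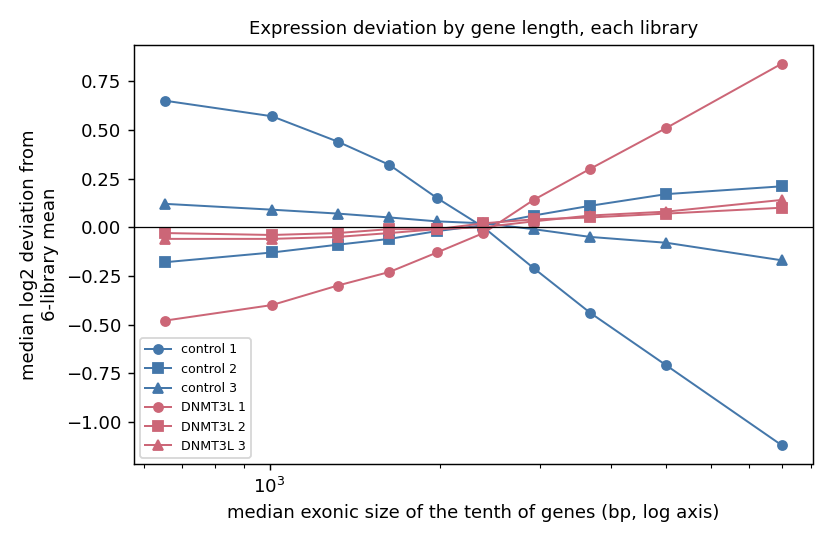
Median log2 deviation from the 6-library mean against the median exonic size in base pairs, on a log axis, for each decile of the tested genes, with 1 line per library. Control 1 goes from 0.65 to −1.12 and DNMT3L 1 from −0.48 to 0.84, while the other 4 libraries stay between −0.18 and 0.21.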

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

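The removal of the length trend, the exclusion of both libraries 1 and voom were chosen after seeing the data. Limma on log2(FPKM + 1), planned for a table without counts, was added beside edgeR after seeing them. Against 0 genes by edgeR with TMM (1427 at an unadjusted p under 0.05), RLE size factors gave 2 genes, all higher, and no low-count filter gave 6, all higher. DESeq2 gave 260 (93 higher, 167 lower). Limma on log2(FPKM + 1) gave 10, all higher, and with its settings changed it gave 5 with pseudocount 0.1, 2 with pseudocount 5, 9 with median-of-ratios scaling, 6 with quantile normalization, 10 with robust shrinkage and 12 without a trend, all higher. Without a filter it gave 12 (11 higher, 1 lower) and with a mean FPKM of 5 it gave 0. Limma array weights gave 4144 (3089 higher, 1055 lower) with a weight of 96.4 on control 3, and the weights did not converge. There Caf1-55 (0.15) and polo (0.24) were called with the opposite sign. Voom with library quality weights gave 1126 (544 higher, 582 lower) with a weight of 6.29 on control 3. Removing the length trend gave 12 (11 higher, 1 lower), and leaving out both libraries 1 gave 23 (16 higher, 7 lower, 4 of these mitochondrial: mt:ND2, mt:ND1, mt:ND3 and mt:srRNA, named after their values were seen). The counts were 0 to 0 when each library was left out. The cause of these differences was not tested, except that fewer libraries or genes enter some of the fits. All 24 genes kept their sign in every setting in which they were tested. They were picked by their p and their groups did not overlap, so leaving out libraries could hardly change a sign.

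The 12 genes after length trend removal became 0 to 14 when each library was left out (0 without control 3, DNMT3L 2 or DNMT3L 3), and 12 and 11 with loess spans of 0.3 and 0.8. The 22 lists became 0 with an estimated correlation, 0 by fry, and 0 with the length trend removed and an estimated correlation. They became 20 with the length trend removed (18 of the 22 kept), and 21 to 23 when each library was left out. Without both libraries 1 they became 22, with 17 kept. Lost were the oxidative phosphorylation, axon guidance, P450, heterochromatin and circadian lists. Gained, all lower, were the lists of ecdysone response (camera adjusted p = 9.45e-05), eye disc (0.00644), Wnt, Hedgehog and Dpp (0.0231), JAK-STAT and JNK stress (0.0231) and heat shock (0.0332). With all libraries the ecdysone list had the other direction and was not called (camera adjusted p = 0.724). None of the 22 lists called with all libraries changed direction in any of these settings.

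Libraries with the same replicate number did not deviate together (correlations of −0.66, −0.54 and −0.18). The opposite length trends of control 1 and DNMT3L 1 enter these correlations, so they cannot show whether the numbers mark a shared day or batch. With the replicate block edgeR gave 0 genes, limma 0, the length-adjusted fit 0 and camera 23 lists. Of 2705 values of the 117 named genes under these settings, 206 in 42 genes changed sign. The planned stricter thresholds for chromosome arms and terms were not run, since edgeR called 0 genes. At this depth and spread the edgeR test recovered 12% of 2-fold changes in the simulation, which drew genes independently. Most changes of that size could thus be missed, and the rate on the real data was not measured.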

Other observations

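All tests in this part were chosen after the results were seen. The 260 genes that DESeq2 called, 249 of which were in the edgeR test and had the same sign there, held 4 functional terms among the lower genes and 0 among the higher, of 847 terms tested by one-sided Fisher's exact tests with Benjamini-Hochberg adjustment. The terms are those of the deposited table, which were not checked against another annotation and look unrelated to the gene in at least 1 case, so these values depend on that annotation. The 4 terms were larval cuticle structure (6 of 27 genes, adjusted p = 0.00216), oxidation-reduction (18 of 367, adjusted p = 0.00411), serine endopeptidase activity (10 of 149, adjusted p = 0.022) and proteolysis (15 of 322, adjusted p = 0.022). By two-sided Fisher's exact test no chromosome arm passed: 28 of 1755 genes on X were called (1.6%, adjusted p = 0.0555) and 68 of 2141 on 2R (3.18%, adjusted p = 0.0555). Mitochondrial transcripts took 1.58%, 3.18% and 4.94% of counts in control libraries 1 to 3 and 2.82%, 2.62% and 2.53% in DNMT3L libraries 1 to 3. Salivary gland genes deviated from their 6-library mean by medians of 0.27, −1.45 and −0.37 in controls 1 to 3 and by −0.75, 0.87 and 1.89 in DNMT3L 1 to 3.

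Of the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05, all 10 gave at least the 0 genes of the real split by edgeR (highest other 0). With the length trend removed 1 split, the real one, gave as many as its 12 genes (highest other 1), and 4 splits gave as many as its 22 called lists (highest other 23). Splits other than the real one called 9 to 23 lists.

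Long genes were higher and short genes lower in DNMT3L, but without control 1 and DNMT3L 1 the difference between the longest and the shortest decile of genes was 0.11 on the log2 scale, against 1.09 with all libraries, so most of the trend may come from these libraries. List medians were set against the central 95% of 10000 random lists matched on exonic size. Over receptors, ion channels and synaptic release the median was 1.15 against 0.36 to 0.60, and for ribosomal proteins −0.66 against −0.44 to −0.26 (gene permutation p = 0.0002 for each, the smallest these lists can give). Neuropeptides (0.44 against −0.46 to −0.16), cuticle (−1.32 against −0.48 to −0.21), muscle (matched range −0.13 to 0.41) and, narrowly, oxidative phosphorylation (−0.48 against −0.44 to −0.22) lay outside too. Axon guidance (0.67 in 0.34 to 0.69), polycomb and trithorax (0.53 in 0.13 to 0.54) and neuroblast genes (0.42 in −0.05 to 0.49) lay within, so length alone stays open for them. Random lists treat genes as independent, while list members moved together (estimated correlation 0.91 for receptors and 0.92 for ribosomal proteins). Matched ranges without control 1 were not computed. With the length trend removed and an estimated correlation, camera gave an adjusted p of 0.56 for both lists. The ranges thus cannot show that a group difference beyond length exceeds the spread between libraries. Length-adjusted neuronal genes exceeded glial genes by 0.82 (95% bootstrap interval 0.58 to 1.08, with genes resampled as if independent). By library means the excess was 0.86 ± 0.33 (SE), or 0.56 without control 1. Dilution of all brain cells by other tissue in the controls would lower both lists alike only if that tissue does not express the glial genes. Whether it does was not tested, so these values cannot decide on dilution. An effect of DNMT3L on neurons, a difference in stage or dissection between samples, and RNA quality stay open and were not tested.

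The 17 genes of the 24 with a log2 fold change above 2 had control means of 3.06 CPM or less and were higher in every DNMT3L library. In a fit over all genes without control 1 and DNMT3L 1, edgeR called 10 of them, all higher. The other 7, though not called there, had log2 fold changes from 2.18 ± 0.55 (SE) upward (Grik, 2.51 with all libraries). The difference was thus not confined to control 1 and DNMT3L 1. Since the genes were picked by their p over all libraries, the fit is not independent support. For Fbp2, a larger amount of carried-over fat body in DNMT3L is argued against. Fbp1, Lsp1alpha, Lsp1beta, Lsp1gamma and Lsp2 had a median of −1.16 (from −1.72 to −0.96). Such genes were still detected in DNMT3L (Lsp1gamma at 176 ± 32.5 CPM). A different Fbp2 level within carried-over fat body thus stays open and was not tested. Strain differences on the crossed chromosomes may account for some of these genes. Among them, 4 pairs lay within 1 Mb of each other, against 2.36 in random gene sets (permutation p = 0.2). CG32581, CR44383 and CG9123 on X paired with each other, and the remaining pair was Unc-115b with CG12592 on 3R. Scattered differences between strains need no such pairs, so strain and transgene cannot be told apart for these genes. An effect of DNMT3L on their expression stays open as a hypothesis.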
